A study of Homo sapiens with 12 samples.

How the data were processed

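HAP1 and RPE-1 cells were cultured for 48 h and treated for 6 h with 50 µM cycloheximide or with DMSO, per the labels' protocols. Stranded poly(A) libraries were made from 500 ng of RNA with RNA integrity numbers of at least 9 (median 9.7) and 11 cycles of PCR, with a library size of 502 bp, per the labels' protocols. Libraries were assigned to the 4 groups by their titles, 3 to a group. The labels number the replicates but do not say that they are separate cultures, so p-values measure only the spread between these samples. Intervals given for shares and odds ratios cover counting error alone.

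The authors deposited an expression table with RPKM per group of 3 libraries. Its log2 fold changes, p-values and FDR come from the authors' own test. Trimmomatic 0.33, Salmon 1.10 and edgeR are named in the submitters' processing notes. The table lists 62269 genes, 22643 with a test and 20824 without a symbol. The authors deposited a vast-tools table with inclusion or intron retention in percent per event and library, with the counts of junction reads behind it, per the file headers. The deposited rMATS tables hold an inclusion difference, a score between -1 and 1, with p-values and FDR, per the file headers, and do not say which group is sample 1. A further deposited score of significance per splicing event has a meaning not given in the sources used here, and mutually exclusive exons were not used here. Versions of vast-tools and rMATS and the genome build are not given in the sources used here. The coordinates match GRCh38, where 78.49% of tested exons and 99.99% of tested introns have an exact match in GENCODE 29.

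The plan, written before the data were examined, assumed expression values per library. The edgeR test of the plan and its DESeq2 alternative were not run, because the expression table pools the libraries. Instead, reads across exon to exon junctions, taken from the vast-tools table, were summed per gene and library. These 33439862 to 39629681 reads per library were scaled with TMM factors, computed in R. Genes with at least 1 junction RPM (reads scaled to library size) in at least 3 libraries were kept (12770). Log2 of junction RPM plus 1 was fitted with limma-trend (limma 3.58.1, R 4.3.3) on all 12 libraries, for cycloheximide against DMSO in each line, for the difference between these changes and for the lines in DMSO. Genes were called at an adjusted p (Benjamini-Hochberg) under 0.05 and an absolute log2 change of at least 1. Adding 1 understates changes of low genes, genes without introns are not measured, and reads of paralogs and pseudogenes, as of histone and ribosomal protein genes, cannot be told apart. Replicates correlated at 0.983 to 0.999 (Pearson).

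Before the data were examined, 20 gene lists were fixed: NMD factors, snoRNA hosts, NMD target mRNAs, immediate-early genes, NF-kB, p53 and ATF4 targets, the unfolded protein response, heat-shock chaperones, cholesterol synthesis, histones, ribosomal proteins, ribosome biogenesis, splicing factors with poison exons, genes known for detained introns, speckle proteins, cell cycle genes, epithelial and mesenchymal markers, haematopoietic markers and interferon genes. They were tested with camera of limma at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives.

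Splicing events (cassette exons, introns, and alternative splice sites) with at least 10 reads in every library were tested per line on 6 libraries, and between lines on 12. The log2 ratio of inclusion to exclusion reads, 0.5 added to each, was fitted with limma and called at an adjusted p under 0.05 within its class and a difference of at least 10 percentage points. The deposited percentages were recomputed from the reads in 5091190 cells, and differed by at most 0.050 points. Exon lengths and retained introns were compared with two-sided Fisher's exact tests (scipy 1.17.1), and overlap with rMATS was counted by coordinates.

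Named genes were chosen by a rule fixed beforehand: the 10 largest changes in each direction per line and the 5 largest between lines among called genes with a symbol and at least 5 RPKM in the higher group, taken from the authors' deposited table. List examples are the members with the smallest adjusted p. For splicing, the 5 largest events in each direction and class were named, 1 per gene, and events of up to 10 splicing factor genes. Some genes meeting the rule are left unnamed.

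The gene and splicing tests were tested on simulated data. With 12152 genes in HAP1 and 12151 in RPE-1, all 50 genes changed by a log2 of 1 were significant and 38% and 36% passed the size threshold, while 100% and 98% did at 1.5. With 121935 exons in HAP1, 28% of those changed by 15 points and 88% of those changed by 40 points were called, and 42% and 90% with 122406 exons in RPE-1. Each size of change had 50 exons, and 28 of 121735 unchanged exons in HAP1 and 43 of 122206 in RPE-1 were also called. For splice sites, 30 of 86909 and 41 of 87734 unchanged ones were called. Far fewer changes were planted than were called in the data, so these shares may not carry over. Alternatives covered scaling, filters, the added constant, thresholds, the list test, read minimum, balanced introns, a replicate block and leaving out each library. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9, statmod 1.5.0 and version 1.17.8 of the package data.table were also used.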

Results

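Stranded, poly(A)-selected RNA sequencing was carried out on HAP1, a near-haploid line derived from a chronic myeloid leukaemia, and on RPE-1, a retinal pigment epithelial line immortalised with telomerase. Each line was treated for 6 h with 50 µM cycloheximide, which stalls translating ribosomes and thereby blocks nonsense-mediated decay (NMD), the translation-dependent removal of mRNAs with premature stop codons, or with its solvent DMSO. There were 3 libraries in each of the 4 groups, 12 in all. The libraries held 33439862 to 39629681 reads across splice junctions, and 12770 genes passed the expression filter. Values per group are means ± SD of 3 libraries, gene levels are junction reads scaled to the library (junction RPM), and log2 changes carry their standard error where given. Coordinates are GRCh38 and gene and exon annotations are those of GENCODE 29.

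The first question was which genes changed when translation was blocked in HAP1. Changes are ranked here on log2 values with 1 RPM added, which understates genes near 0 RPM. The largest fall was that of HSPA8, the constitutive Hsp70 chaperone (chromosome 11, 123057489 to 123063230), from 5289.9 ± 354 to 58.6 ± 0.758 junction RPM (log2 change -6.47 ± 0.06, limma adjusted p = 1.60e-14). WNK4, a kinase that regulates ion transport (chromosome 17, 42780678 to 42796936), had the largest rise on this scale, from 1.69 ± 0.248 to 181 ± 8.59 (log2 change 6.08 ± 0.10, adjusted p = 1.83e-12). Of the fixed lists, heat-shock chaperones had 8 of 11 members lower, the unfolded protein response 4 of 15 and ribosome biogenesis 6 of 23, and genes known for detained introns had 11 of 30 higher. These 4 list calls were lost with an estimated correlation between genes (adjusted p = 0.0620 to adjusted p = 0.159). In all, 1398 genes were higher and 1773 lower. That balance depended on scaling, with 1654 higher and 1539 lower when scaled to total junction reads.

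The other large rises in HAP1 were those of LAT2, an immune adaptor (5.80 log2, from 0.188 ± 0.0728 to 65.1 ± 4.47 junction RPM, and 8.13 in the authors' deposited table, where WNK4 has 6.58), AVIL, an actin-binding protein (4.92), the phospholipase PLA2G4C (4.84), the mitochondrial aldehyde dehydrogenase ALDH2 (4.82) and the oviductal glycoprotein OVGP1 (4.70). The cholesterol transporter NPC1L1 (4.68), muscle glycogen phosphorylase PYGM (4.50), POPDC2 (4.47) and the short-chain dehydrogenase DHRS2 (4.40) completed the 10 largest. After HSPA8, the largest falls were those of the glycosyltransferase GALNT18 (-4.48), CAPN15 (-4.08), the neuronal pentraxin NPTX1 (-4.03), the T-box factor TBX1 (-3.90) and the acyltransferase LPCAT1 (-3.84). The Hsp40 co-chaperone DNAJB1 (-3.74), XYLT2 (-3.71), TOMM40L (-3.70) and DGCR2 (-3.66) followed.

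Among the gene lists fixed beforehand, heat-shock chaperones moved furthest in HAP1: 8 of 11 fell (median log2 change -1.42, camera adjusted p = 1.39e-04), with DNAJB1 at -3.74 ± 0.07, DNAJA1 at -2.86 ± 0.08 and the Hsp90 gene HSP90AB1 at -1.60 ± 0.07. That call was lost with an estimated correlation between genes (adjusted p = 0.0876). Of 15 genes of the unfolded protein response, 4 fell, among them the chaperones PDIA4 (-2.43 ± 0.06) and HSPA5 (-2.16 ± 0.06) and the transcription factor XBP1 (-1.88 ± 0.08). The median of the list was -0.85 (adjusted p = 1.39e-04, or adjusted p = 0.0620 with an estimated correlation). Ribosome biogenesis genes had a median of -0.78 (adjusted p = 0.0239, or adjusted p = 0.159 with an estimated correlation). 6 of 23 fell, including the nucleolar proteins GNL3 (-2.14), NOP16 (-1.83) and NCL (-1.24). Of 30 genes known for detained introns, 11 rose and 2 fell (median 0.66, adjusted p = 0.00324, or adjusted p = 0.0876 with an estimated correlation). The splicing kinase CLK1 (2.06 ± 0.07), the cyclin CCNL1 (2.49 ± 0.09) and the splicing regulator TRA2A (1.61 ± 0.06) rose, whereas MAT2A, which makes S-adenosylmethionine, fell (-2.96 ± 0.07).

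The other 16 lists did not pass camera in HAP1, although single members changed. Immediate-early genes, which transcription induces without new protein, had 5 members higher and 5 lower of 40 (median 0.10, adjusted p = 0.464), with KLF10 at 4.38, ATF3 at 2.03 and FOSL1 at -1.91. Of 21 NF-kB targets, RELB rose (2.84) and NFKB1 fell (-1.31; list adjusted p = 0.708). Known NMD target mRNAs had 7 of 21 higher, such as ATF4 (1.76) and GADD45A (2.09), and 2 lower (adjusted p = 0.156). Of 20 snoRNA host genes, 5 rose, including SNHG1 (1.29) and SNHG17 (2.24), and SNHG16 fell (-2.42; adjusted p = 0.127). The authors' deposited table has 3 higher and 5 lower of 21 snoRNA hosts in HAP1. The NMD factors had 2 of 10 higher, UPF2 among them (1.21; adjusted p = 0.301). For p53 targets the counts were 4 higher and 6 lower of 24 (DDB2 3.55, PLK3 -2.94; adjusted p = 0.841). For ATF4 targets they were 1 and 7 of 27, with the amino acid transporter SLC7A5 at -3.22 (adjusted p = 0.127).

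Cholesterol synthesis had 4 genes higher and 6 lower of 23 in HAP1, with SQLE at -1.86 and HSD17B7 at 1.46 (adjusted p = 0.301). Splicing factors with poison exons, whose inclusion brings a premature stop codon, had 4 higher and 3 lower of 43 (adjusted p = 0.301), SRSF10 (1.33) and LUC7L (-1.38) being examples. Of 25 cell cycle genes, 6 fell, including CCNB1 (-2.10), and 2 rose, including MCM2 (1.53; adjusted p = 0.395). The 3 histone genes with measurable junctions had a median of 1.35, and HIST1H2BD (1.86) and HIST1H2AC (1.35) rose (adjusted p = 0.0514). Of 78 ribosomal protein genes, 0 passed the threshold of limma and 19 were lower at an unadjusted p under 0.05 (median -0.21, camera adjusted p = 0.0683). Of 15 speckle proteins, 1 rose (median 0.02, adjusted p = 0.412). Interferon genes had IFI27 alone above the threshold among 12 (1.56, adjusted p = 0.755). Of the haematopoietic markers, 2 of 5 rose, SPI1 (1.51) and GATA2 (1.33), and KIT fell (-2.71; adjusted p = 0.841), with a median of 0.23 and a mean of opposite sign, -0.10. Of 13 epithelial and mesenchymal markers, 0 passed, with 3 higher and 4 lower at an unadjusted p under 0.05; the median was 0.01 and the mean -0.13 (adjusted p = 0.755). The sign of the medians for interferon genes, mesenchymal markers and speckle proteins in HAP1 depended on how the libraries were scaled. Libraries 2 and 3 of the HAP1 DMSO group lay far apart, at -24.1 and 24.2 on an axis of differences inside groups that followed the GC content of genes. In every list and comparison, the counts adjusted over the list alone equalled those over all genes. Junction reads change with splicing as well as with transcript level, and copies with near-identical sequence, as among histone and ribosomal protein genes, may share reads. Called on the adjusted p alone, 3970 genes were higher and 4526 lower in HAP1. There were 1541 higher and 1625 lower with median-of-ratios factors and 1507 higher and 1562 lower with the GC trend removed.

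The same question was asked of RPE-1. ATF3, a stress-induced transcription factor (chromosome 1, 212565334 to 212620777), had the largest rise on the same scale, from 0.914 ± 0.179 to 335 ± 2.34 junction RPM (log2 change 7.46 ± 0.09, adjusted p = 2.38e-13). HSPA8 again had the largest fall, from 1815 ± 20.5 to 62.4 ± 1.02 (-4.84 ± 0.06, adjusted p = 2.38e-13). Of the fixed lists, cell cycle genes had 7 of 25 members lower and genes known for detained introns 11 of 30 higher, and both calls held with an estimated correlation (adjusted p = 0.0481 and adjusted p = 0.0400). In all, 1567 genes were higher and 1028 lower.

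The 10 largest rises in RPE-1 also included the cytochrome CYP1A1 (6.72), the transcription factors MAFF (6.69), FOS (5.84), EGR1 (5.46) and NR1D1 (5.69), and DHRS2 (5.27). PPP1R15A, which directs dephosphorylation of the initiation factor eIF2α, rose by 5.20, the chemokine CXCL8 by 5.03 and the stress gene GADD45B by 5.02. After HSPA8, the largest falls were those of lamin B1, LMNB1 (-4.65), LPCAT1 (-3.65), LRFN3 (-3.33), MXD3 (-3.24), FAM20C (-3.07), FUT8 (-3.07) and EPHB4 (-3.07). DDIT4, an inhibitor of mTORC1 (-3.01), and MMP15 (-2.97) were next.

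Of 40 immediate-early genes, 31 rose in RPE-1 (median 1.79, camera adjusted p = 1.14e-13, or adjusted p = 0.0539 with an estimated correlation), EGR2 (3.86 ± 0.07), EGR1 and MAFF among them. NF-kB targets rose in 18 of 21 cases (median 2.49, adjusted p = 2.66e-11, or adjusted p = 0.0539 with an estimated correlation). Examples are TNFAIP3, a feedback inhibitor of the pathway (4.90 ± 0.14), BIRC3 (4.35 ± 0.08) and IL1A (3.83 ± 0.07). Known NMD target mRNAs rose in 10 of 21 cases, such as GADD45A (4.89 ± 0.13), GADD45B and PPP1R15A (median 0.83, adjusted p = 2.52e-05, or adjusted p = 0.0761 with an estimated correlation). ATF3 is in both the immediate-early and the NMD target lists. All 3 histone genes with measurable junctions rose (HIST1H2AC 3.29 ± 0.08; median 3.06, adjusted p = 9.88e-04, or adjusted p = 0.0539 with an estimated correlation).

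Of 30 genes known for detained introns, 11 rose in RPE-1, including CCNL1 (3.48 ± 0.09), CLK4 (3.03 ± 0.08) and CLK1 (2.65 ± 0.07), and MAT2A fell (-1.53 ± 0.07). This list (median 0.58, adjusted p = 3.76e-06) held with an estimated correlation (adjusted p = 0.0400). Splicing factors with poison exons had 7 of 43 members higher, PTBP2 (2.61) and RBM5 (1.36) among them (median 0.38, adjusted p = 9.21e-04, or adjusted p = 0.0885 with an estimated correlation). Speckle proteins had 3 of 15 higher, such as the kinase PRPF4B (1.37; median 0.52, adjusted p = 0.0136, or adjusted p = 0.0539 with an estimated correlation). Ribosome biogenesis genes had a median of 0.40 and 2 of 23 rose, RRP12 (1.79) being an example (adjusted p = 0.00477, or adjusted p = 0.0539 with an estimated correlation).

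Cell cycle genes fell in 7 of 25 cases in RPE-1, among them the cyclins CCNA2 (-2.19 ± 0.07) and CCNE1 (-1.76 ± 0.09) and the mitotic kinase PLK1 (-1.95 ± 0.12). The list (median -0.67, adjusted p = 8.73e-05) also held with an estimated correlation (adjusted p = 0.0481). Of 23 cholesterol synthesis genes, 12 fell, including SQLE (-1.58 ± 0.09), MSMO1 (-2.07 ± 0.14) and NSDHL (-1.28 ± 0.08). The median was -1.02 (adjusted p = 9.88e-04, or adjusted p = 0.0507 with an estimated correlation). The unfolded protein response had 2 of 15 genes lower, XBP1 (-2.06) and PDIA4 (-1.10), with a median of -0.68 (adjusted p = 9.88e-04, or adjusted p = 0.0507 with an estimated correlation). Heat-shock chaperones had 3 of 11 lower, HSPA8, DNAJB1 (-2.38) and DNAJA1 (-1.60), with a median of -0.62 (adjusted p = 0.0220, or adjusted p = 0.155 with an estimated correlation). Ribosomal protein genes had a median of -0.60, and 2 of 78 passed the threshold, RPS23 (-1.10) among them (adjusted p = 4.11e-09, or adjusted p = 0.375 with an estimated correlation).

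The remaining 7 lists did not pass in RPE-1. The p53 targets had 9 higher and 2 lower of 24, with AEN at 2.40 and PMAIP1 at 2.83 (adjusted p = 0.0649). The ATF4 targets had 4 higher and 4 lower of 27, SLC7A5 at 2.64 and DDIT3 at 1.86 being examples (adjusted p = 0.527). Of the snoRNA hosts, 5 of 20 rose, including SNHG1 (2.14) and SNHG15 (1.95; adjusted p = 0.123). Of the NMD factors, the kinase SMG1 rose (2.26; adjusted p = 0.123). Interferon genes had 1 higher and 2 lower of 12, IFI44 at -1.51 (adjusted p = 0.0936). Epithelial and mesenchymal markers had 2 of 13 higher, such as MITF (2.12), and VIM lower (-1.20; adjusted p = 0.217). Haematopoietic markers had 2 of 5 higher, RUNX1 (3.72) and GATA2 (2.58; adjusted p = 0.217). Called on the adjusted p alone, 3880 genes were higher and 4526 lower in RPE-1. DMSO libraries 2 and 3 of RPE-1 lay at 19.6 and -26.4 on the axis inside groups that followed the GC content of genes.

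**Figure D1:**
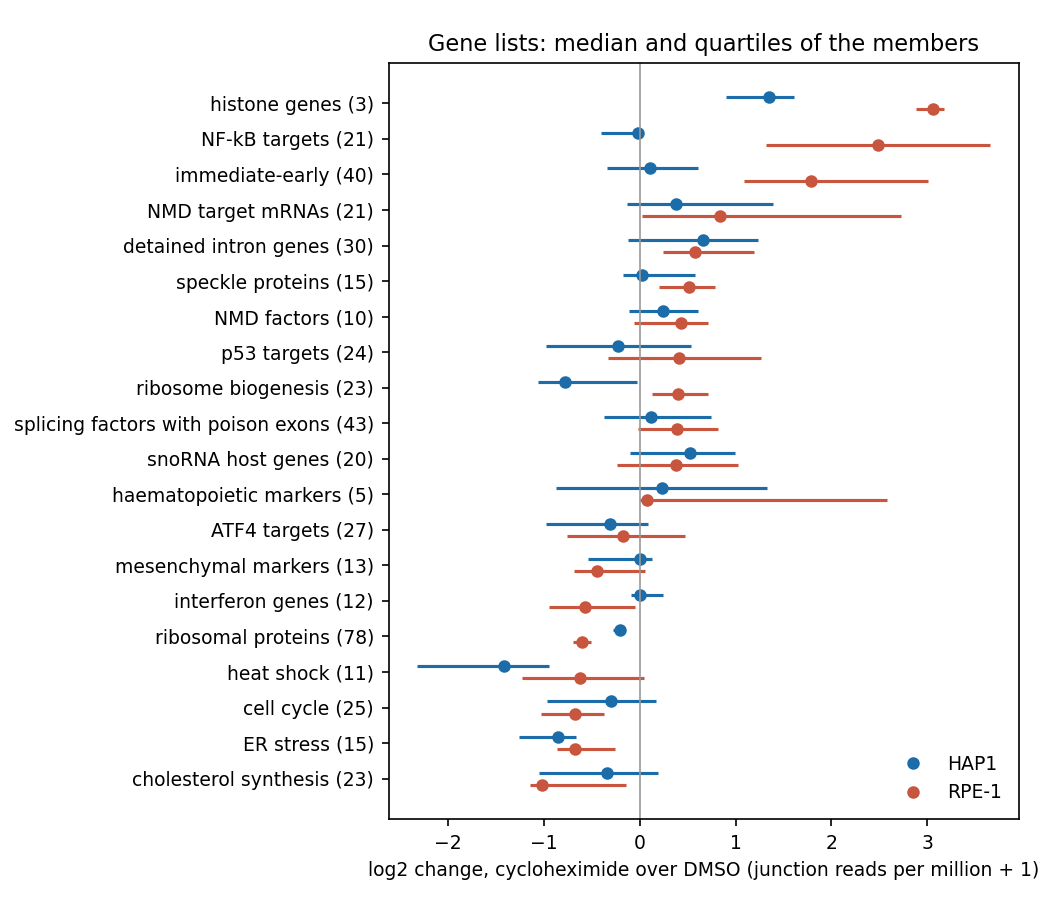
Median (points) and quartiles (lines) of the log2 change of junction RPM with 1 added, cycloheximide over DMSO, for the members of each fixed gene list in HAP1 (blue) and RPE-1 (red), with the number of members in brackets. NF-kB targets had a median of 2.49 in RPE-1 and -0.02 in HAP1, and heat-shock chaperones had -0.62 and -1.42; the sign of the HAP1 medians of interferon genes, mesenchymal markers and speckle proteins depended on scaling.

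Whether the lines responded differently was tested directly, as the change in HAP1 minus the change in RPE-1. NPTX1 fell in HAP1 (-4.03) and rose in RPE-1 (3.93), a difference of -7.95 ± 0.16 (adjusted p = 5.37e-11). SLC7A5 (-3.22 and 2.64) and the histone deacetylase HDAC9 (-1.39 and 4.01) also went in opposite directions, differing by -5.86 ± 0.16 and -5.40 ± 0.17. MAFF (difference -6.09 ± 0.17) and ATF3 (-5.43 ± 0.13) rose more in RPE-1. ALDH2 rose in HAP1 and its change in RPE-1 was -0.89 (difference 5.70 ± 0.16), and GRB7 (5.02), SV2A (4.80), LAT2 (4.72) and NPC1L1 (4.64) followed. In all, the change was higher in HAP1 for 1678 genes and lower for 2325.

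Immediate-early genes (median difference -1.65, adjusted p = 2.02e-09) had a lower change in HAP1 for 26 of 40 members, EGR1 (-4.94) among them, and NF-kB targets (median -2.50, adjusted p = 3.51e-09) for 18 of 21, such as NFKB1 (-3.79). With an estimated correlation, neither list passed (adjusted p = 0.166 for both). Heat-shock chaperones were lower in HAP1 for 6 of 11 members, including HSPA8 (-1.63; median -1.002, adjusted p = 0.00120, or adjusted p = 0.166 with an estimated correlation). Ribosome biogenesis genes differed for 11 of 23, GNL3 (-2.25) among them (median -0.93, adjusted p = 1.28e-04, or adjusted p = 0.0864 with an estimated correlation). NMD targets (median -0.95, adjusted p = 0.0221, or adjusted p = 0.356 with an estimated correlation) had a lower change in HAP1 for 9 of 21, for example PPP1R15A (-4.83). All 3 histone genes did too (median -1.94, adjusted p = 0.0199, or adjusted p = 0.166 with an estimated correlation).

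For cell cycle genes, the change was higher in HAP1 for 9 of 25, such as CCNA2 (-0.52 in HAP1 and -2.19 in RPE-1), and lower for 2 (median difference 0.53, adjusted p = 0.0411, or adjusted p = 0.196 with an estimated correlation). Ribosomal protein genes had a median difference of 0.40, with 0 of 78 past the threshold of limma and 39 higher at an unadjusted p under 0.05 (camera adjusted p = 5.94e-04, or adjusted p = 0.639 with an estimated correlation). The lines shared 308 genes that rose and 384 that fell, where independent lists of the same sizes would share 172 and 143. A further 149 genes fell in HAP1 and rose in RPE-1, against 218 for independent lists, and 28 rose in HAP1 and fell in RPE-1, against 113. Called on the adjusted p alone, 4210 genes had a higher and 4241 a lower change in HAP1.

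The DMSO libraries gave the starting levels of the lines. THBS1, an extracellular matrix protein, was at 0.0993 ± 0.0353 junction RPM in HAP1 and 5001 ± 830.3 in RPE-1, and TGFBI at 0.0914 ± 0.0592 and 3759.8 ± 115. Of the 13 epithelial and mesenchymal markers, 12 were lower in HAP1 (median -6.57, adjusted p = 3.82e-06), and of the 12 interferon genes 10 were, ISG15 (-3.97) among them (median -1.87, adjusted p = 0.00113). All 23 ribosome biogenesis genes were higher in HAP1, for example DKC1 (2.54 ± 0.06) and NCL (2.07 ± 0.08; median 2.07, adjusted p = 7.85e-08). In all, 2626 genes were higher and 2945 lower in HAP1, or 5257 and 5032 on the adjusted p alone. With quantile normalisation the counts were 3042 higher and 2649 lower, and scaled to total junction reads they were 2979 higher and 2688 lower, so which direction was in the majority depended on scaling.

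Cell cycle genes (10 of 25 higher in HAP1, MCM2 at 2.71; adjusted p = 2.51e-04) and speckle proteins (7 of 15 higher; adjusted p = 0.00113) also differed in DMSO. With the markers, interferon genes and ribosome biogenesis genes, these were the 5 lists that held with an estimated correlation (adjusted p from 0.00767 to 0.0265). NF-kB targets (16 of 21 lower; adjusted p = 3.82e-06, or adjusted p = 0.138 with an estimated correlation) and immediate-early genes (5 higher and 22 lower of 40; adjusted p = 2.91e-04, or adjusted p = 0.244 with an estimated correlation) started lower in HAP1. A further 8 lists were called in DMSO and lost. Higher in HAP1 were heat-shock chaperones (8 higher and 2 lower of 11; adjusted p = 0.0103, or adjusted p = 0.147 with an estimated correlation) and snoRNA hosts (10 of 20 higher; adjusted p = 4.38e-04, or adjusted p = 0.253 with an estimated correlation). So were ribosomal protein genes (12 of 78 higher; adjusted p = 2.99e-06, or adjusted p = 0.497 with an estimated correlation) and splicing factors with poison exons (19 higher and 2 lower of 43; adjusted p = 1.55e-05, or adjusted p = 0.05004 with an estimated correlation). Genes known for detained introns (8 of 30 higher; adjusted p = 0.00143, or adjusted p = 0.05004 with an estimated correlation) and ATF4 targets (12 higher and 4 lower of 27; adjusted p = 0.0307, or adjusted p = 0.180 with an estimated correlation) were higher too. Lower in HAP1 were the unfolded protein response (6 of 15 lower; adjusted p = 0.00845, or adjusted p = 0.0686 with an estimated correlation) and p53 targets (2 higher and 11 lower of 24; adjusted p = 0.0458, or adjusted p = 0.104 with an estimated correlation). The cell cycle inhibitor CDKN1A was at 0.305 ± 0.0497 in HAP1 and 257 ± 26.7 in RPE-1. The median change over all genes was 0.03 here, 0.16 with quantile normalisation and 0.14 when scaled to total junction reads, so levels are relative to the scaling used.

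The authors' deposited table, which pools the libraries of a group and covers genes without junctions, was set beside these changes. In the authors' deposited table HSPA8 goes from 2483 to 31.0 RPKM in HAP1 and from 863 to 32.7 in RPE-1. Across 12077 shared genes, which are not independent, the log2 changes of the authors' deposited table and of the junction test had a Pearson correlation of 0.854 in HAP1 and 0.803 in RPE-1. Of the 2984 shared genes called in HAP1, 2971 had the same sign in the authors' deposited table, and in RPE-1 2466 of 2469 did. The authors' deposited table lists 12 of the histone genes, of which 10 are higher in HAP1 (median 2.00) and 12 in RPE-1 (median 3.22).

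The next question was which exons, introns and splice sites changed after cycloheximide in HAP1. How far the drug blocked NMD in these cells was not measured. An exon of RSRC2, a gene of the detained-intron list (chromosome 12, 122520504 to 122520581, 78 nt, coding), went from 10.3% ± 0.558 to 87.2% ± 0.715 inclusion (adjusted p = 2.60e-04). An exon of ANKRD52 (chromosome 12, 56248023 to 56248224, coding) went the other way, from 98.8% ± 0.586 to 19.4% ± 7.996 (adjusted p = 4.11e-04). Exons moved about equally often in both directions, 2950 higher and 2899 lower of 121935 tested. Introns mostly lost retention, 2595 lower and 524 higher of 97422. Of 87109 alternative splice sites, 594 were higher and 597 lower, where the sites of an event share 100% and a rise of a site is a fall of another.

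Among the largest rises of exon inclusion in HAP1, besides RSRC2, were those of RABGAP1 (chromosome 9, 123071412 to 123071501, 90 nt, found only in transcripts annotated as NMD targets), from 5.48% ± 3.72 to 83.4% ± 5.17, MAP3K21 (3.48 to 78.9%), a 24-nt microexon of the kinase CSNK1G3 (5.82 to 80.8%) and NUP50 (1.42 to 75.7%). The largest falls, besides ANKRD52, were those of GIGYF1 (84.5 to 3.85%), the splicing kinase CLK3 (chromosome 15, 74622125 to 74622216; 96.8 to 18.05%), the repressor CIC (95.3 to 16.6%) and CYTH3 (98.4 to 20.05%). Of the 2899 exons that fell, 2135 had been included at 90% or more in DMSO. Retention rose in introns of TIGD3 (12.9 to 92.2%), EFNA2 (3.19 to 75.2%), UXS1 (12.9 to 81.7%), RSRC2 (9.48 to 74.3%) and the blood transcription factor GATA2 (9.55 to 72.2%). It fell in NECAB3 (96.6 to 9.60%), DYRK4 (90.2 to 6.45%), the GABA receptor gene GABBR1 (90.1 to 14.9%) and VWA7 (82.3 to 7.48%). Several of these events rest on few reads. The library with the fewest had 12 for NUP50, 13 for GATA2, 15 for MAP3K21 and VWA7 and 16 for TIGD3, against 946 for the RSRC2 exon. The SD was 15.6 points for VWA7 in DMSO and 12.3 for MAP3K21 after cycloheximide. Only introns are dropped when balanced reads are required, and 66 of the 80 named events were left. Most of the introns named in HAP1 and RPE-1 thus did not have balanced reads. The RSRC2 interval (122519030 to 122521384) holds the RSRC2 exon whose inclusion rose, so retention of that whole intron was not shown. Splice site use rose in KIAA0430 (8.94 to 75.2%), KNOP1 (21.7 to 87.1%) and PPCS (9.51 to 73.6%) and fell in LENG8 (97.9 to 29.2%).

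Splicing factors with poison exons changed in HAP1 in 28 of 43 genes, with 36 exons higher and 4 lower. An exon of SRSF5 (chromosome 14, 69769511 to 69769847) rose from 6.02% ± 0.479 to 70.4% ± 1.05, and NMD-only exons rose in HNRNPLL (0.937 to 41.9%), SRSF11 (3.45 to 41.5%) and SRSF4 (chromosome 1, 29168503 to 29168638; 3.60 to 38.5%). LUC7L rose from 2.91 to 56.6%, while a coding exon of PTBP2 fell (86.8 to 23.9%). The number of introns that fell was 1428 on the percentage scale, 1670 at a threshold of 15 points and 1415 among introns with balanced reads. Of the last, 170 rose, and on the percentage scale splice sites numbered 302 higher and 317 lower. Splice sites that rose numbered 389 without cycloheximide replicate 3, and those that fell 388 without replicate 1 and 378 without replicate 3.

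**Figure D2:**
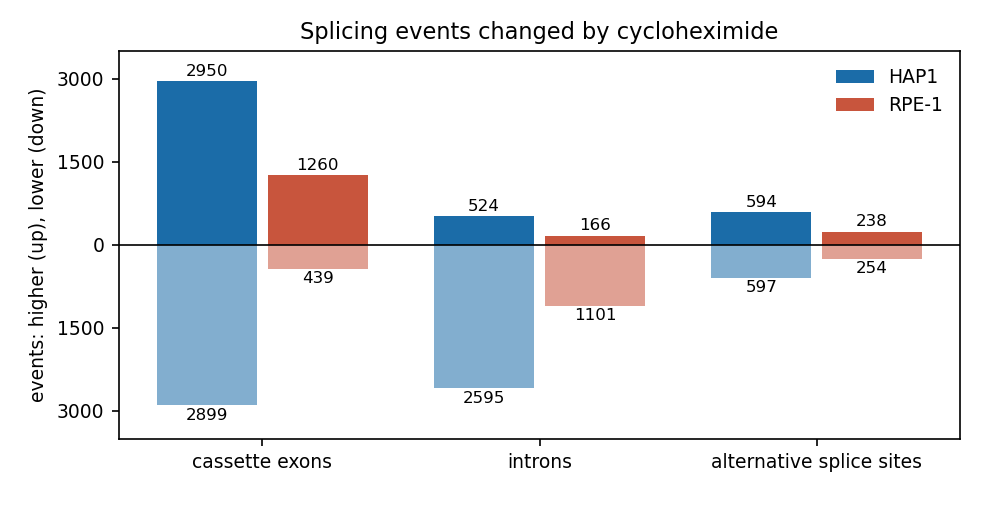
Number of splicing events called higher (bars upward) and lower (pale bars downward) after cycloheximide in HAP1 (blue) and RPE-1 (red), by class of event. Exons that fell numbered 2899 in HAP1 and 439 in RPE-1, and introns that fell 2595 and 1101.

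In RPE-1 the same comparison gave fewer changes, and exons mostly gained inclusion. An exon of PHACTR2 (chromosome 6, 143760401 to 143760640, 240 nt, coding) went from 16.1% ± 4.52 to 87.05% ± 4.41 (adjusted p = 0.00224), and an intron of the snoRNA host SNHG12 (chromosome 1, 28579588 to 28579911, noncoding transcript) from 71.6% ± 7.08 to 6.20% ± 2.12 retention (adjusted p = 0.00444). Of 122406 exons, 1260 were higher and 439 lower, and of 97965 introns 166 were higher and 1101 lower. Of 87934 alternative splice sites, 238 were higher and 254 lower.

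Inclusion in RPE-1 also rose in PHACTR4 (7.63 to 78.1%), FNBP4 (15.4 to 83.7%), IVNS1ABP (10.1 to 74.8%) and FBXO43 (36.8 to 100.0%), and fell in RABGAP1L (64.7 to 15.01%), the catenin gene ARVCF (56.4 to 9.06%), ZNF211 (82.5 to 38.1%), KIN (96.6 to 53.1%) and ZNF577 (65.6 to 23.3%). Retention rose in ZNF436 (37.7 to 83.8%), RNF166 (9.44 to 55.4%), EMC9 (16.5 to 62.2%) and the sterol isomerase gene EBP (15.1 to 60.5%), and fell in PDE4DIP (79.7 to 16.1%), ZNF692 (84.03 to 25.97%) and the DNA glycosylase NEIL1 (76.2 to 19.1%). Across the introns named in HAP1 and RPE-1, most did not have balanced reads. Splice site use rose in ENTPD4 (9.15 to 65.5%) and SLC7A6OS (21.98 to 70.1%) and fell in HEXIM2 (79.3 to 14.5%) and KLHL36 (89.2 to 35.99%). Several events named in RPE-1 also rest on few reads. The library with the fewest had 10 for FBXO43, 12 for PHACTR4 and HEXIM2, 13 for ZNF577 and 14 for ARVCF and ZNF211, against 128 for ENTPD4. For ZNF692 the SD after cycloheximide was 13.8 points.

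Of 43 splicing factor genes with poison exons, 19 changed in RPE-1, with 20 exons higher and 2 lower. Exons rose in HNRNPDL (20.2 to 75.7%, NMD-only), SRSF6 (12.7 to 64.6%), HNRNPD (2.39 to 48.7%) and SRSF4 (4.05 to 38.6%, NMD-only), and a coding exon of U2SURP fell (96.03 to 62.96%). On the percentage scale 675 exons were higher, 175 lower and 464 introns lower, and at 15 points 765, 270 and 609. Introns that rose numbered 33 among those with balanced reads and 89 on the percentage scale, where splice sites numbered 69 higher and 60 lower. Introns with balanced reads that fell numbered 609. Exons that fell numbered 275, 274 and 257 without cycloheximide replicate 1, 2 or 3, and introns that fell 708 without cycloheximide replicate 2 and 660 without DMSO replicate 1. Without cycloheximide replicate 1, 2 or 3, or DMSO replicate 1, higher introns numbered 100, 102, 96 and 108, higher splice sites 109, 116, 114 and 141, and lower splice sites 102, 116, 113 and 138.

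The difference between the lines in splicing was tested as the change in HAP1 minus that in RPE-1. The CSNK1G3 microexon rose in HAP1 and fell in RPE-1, from 65.8% ± 1.49 to 32.5% ± 5.28, a difference of 108 points (adjusted p = 1.09e-05). The RSRC2 exon stood at 11.6% ± 0.203 and 17.7% ± 1.40 in RPE-1 (difference 70.8 points, adjusted p = 5.71e-06), and the CLK3 exon at 95.96% ± 2.28 and 97.5% ± 0.370 (-80.3 points, adjusted p = 2.88e-05). For the SRSF4 exon no difference between the lines was detected (adjusted p = 0.658), nor for that of IVNS1ABP (adjusted p = 0.881). In all, 1481 exons had a higher and 2142 a lower change in HAP1, of 107898 tested in both lines. For splice sites the counts were 207 and 195 of 77682, and for introns 416 and 765 of 85379, where 5 of 100 regroupings of the libraries called as many and all 5 kept the treatment split of HAP1.

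Of the exons lower in HAP1, 2615 were tested in RPE-1, where their median change was -0.00667 points. Their median in HAP1 was -19.7, but there they were selected for falling by at least 10 points. Both lines lowered 108 exons and raised 381, and 67 exons that fell in HAP1 rose in RPE-1. Both lowered the retention of 568 introns. Numbers of introns in the difference were 256 and 503 at 15 points and 160 and 294 with balanced reads. Numbers of splice sites were 377 and 371 with 2 reads added, and 122 and 126 when adjusted over events at 5 to 95%, a setting chosen after the data were seen.

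An exon whose length is not a multiple of 3 shifts the reading frame when it is gained or skipped, so exon lengths were compared between called and other exons. Exons that fell in HAP1 had lengths divisible by 3 in 29.01% of cases, against 38.5% of exons not called (odds ratio 0.653, 95% interval 0.602 to 0.708, two-sided Fisher's exact p = 4.75e-26). In RPE-1 the share was 23.5% (odds ratio 0.486, 0.390 to 0.606, exact p = 1.66e-11). For exons that rose, no difference passed in HAP1 (40.1%, odds ratio 1.07, exact p = 0.0847) or RPE-1 (39.5%, odds ratio 1.04, exact p = 0.542). At 15 points the HAP1 odds ratio was 1.11 (exact p = 0.0226) and at 20 reads 1.09 (exact p = 0.0324), past the threshold. In RPE-1 the odds ratio for exons that rose was under 1 without cycloheximide replicate 1 (0.973) or 3 (0.987) and without DMSO replicate 1 (0.976) or 2 (0.927).

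Introns detained in control cells were followed next, taking as retained those at 15% or more in the DMSO libraries of the other line. Of 3015 such introns, 998 lost retention in HAP1 (33.1%), against 1.30% of 82364 others (odds ratio 37.6, 95% interval 34.1 to 41.4). In RPE-1 687 of 3928 did (17.5%), against 0.211% of others (odds ratio 100.2, 84.4 to 119). Introns of GABBR1 and SNHG12 are examples. Most other introns were too low in DMSO to fall by 10 points. Among introns with room to fall, the HAP1 odds ratio turned to 0.710 (exact p = 1.31e-09) and that of RPE-1 to 1.07 (exact p = 0.509), a comparison chosen after the data were seen. Room was judged in the same DMSO libraries that enter the change. Introns high there by error would fall back, so this comparison cannot decide whether retained introns fell more often. The retention of introns at 15% or more in the other line, with their reads pooled in each library, went from 76.2% ± 0.847 to 70.9% ± 0.346 in HAP1 and from 61.7% ± 1.40 to 60.8% ± 0.734 in RPE-1, the latter within the spread of the libraries. Pooling gives introns with many reads more weight. Averaged over the same introns, retention went from 59.3 to 49.2% in HAP1 and from 45.2 to 39.8% in RPE-1, and 63.2% and 66.3% of them fell. Pooled retention of introns under 5% in the other line went from 0.581% ± 0.173 to 0.397% ± 0.0110 in HAP1 and from 0.348% ± 0.0210 to 0.252% ± 0.00527 in RPE-1. HAP1 DMSO replicate 2, at 0.407%, lay at the level of the treated libraries.

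**Figure D3:**
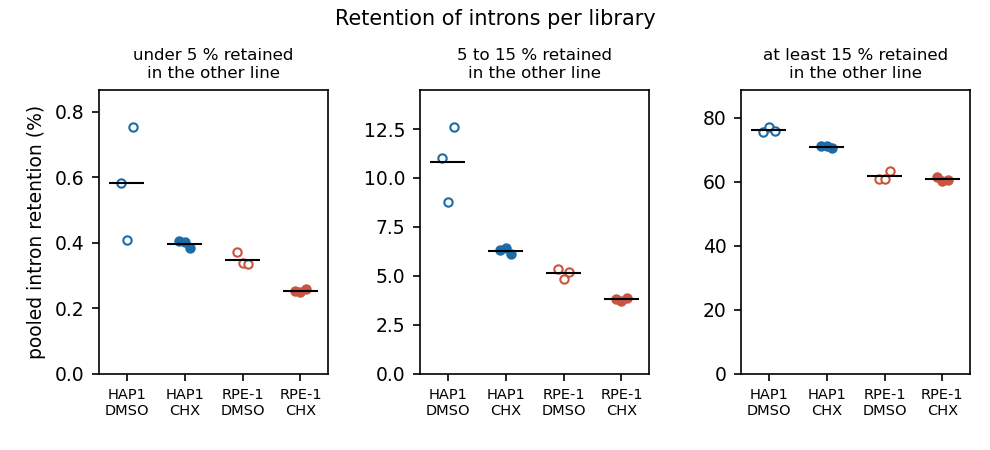
Pooled retention in percent of introns in each library (open points DMSO, filled points cycloheximide; lines are group means), for introns grouped by their mean retention in the DMSO libraries of the other line. Introns under 5% and at 5 to 15% were lower after cycloheximide in both lines, and DMSO replicate 2 of HAP1 stood at 0.407%, beside 0.384 to 0.405% in the treated libraries.

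The calls were set beside the authors' deposited lists of splicing events from rMATS, a second splicing tool. Of 5250 called HAP1 exons that rMATS had tested, 79.1% were in the authors' deposited list (95% Wilson interval 78.0 to 80.2), against 4.33% of exons not called. For HAP1 introns the share was 82.8% of 716, against 1.92%, and in RPE-1 73.1% of 1477 exons and 82.3% of 351 introns. The headers do not say which group was subtracted from which, so these shares count overlap without direction. Read as cycloheximide minus DMSO, 4132 of the shared HAP1 exons had the same sign in the authors' deposited list and 22 the opposite, and 1077 and 2 in RPE-1.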

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

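The results here were singled out because a test of the difference itself, the change in HAP1 minus that in RPE-1, passed its threshold. The split tests for genes were chosen only after the result was seen; the other tests below were written down before. The change was higher in HAP1 for 1678 genes and lower for 2325, higher for 1481 exons and lower for 2142, higher for 416 introns and lower for 765, and higher for 207 splice sites and lower for 195. Median differences were -0.95 for NMD targets, -1.65 for immediate-early genes, -2.50 for NF-kB targets, -1.002 for heat-shock chaperones, -1.94 for histones, 0.40 for ribosomal proteins, -0.93 for ribosome biogenesis and 0.53 for the cell cycle. None of these lists passed with an estimated correlation. Single genes were ALDH2 (5.70), GRB7 (5.02), SV2A (4.80), LAT2 (4.72), NPC1L1 (4.64), NPTX1 (-7.95), MAFF (-6.09), SLC7A5 (-5.86), ATF3 (-5.43) and HDAC9 (-5.40).

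Regrouping the 12 libraries inside each line gave as many calls in 2 of 100 splits for genes, exons and splice sites and in 6 of 100 for introns, the real grouping included. For genes the real grouping called 4003, the split that exchanges the treatment labels of a line called 5564, and the next 2970. For exons these were 3623, 5850 and 2800, for splice sites 402, 1718 and 329, and for introns 1181, 4009 and 1844. The other splits with as many calls kept the treatment split of HAP1, so they carry the treatment effect and show the structure of the samples. Among 75 splits keeping neither treatment split, limma called at most 0 genes, 1 exon, 0 introns and 2 splice sites. These splits put treated and control libraries in both groups, so the treatment effect widens the spread and few calls can arise. Their low counts therefore do not measure chance. For introns the 6 of 100 are over the share of 0.05 set beforehand, but the 5 other splits hold the treatment effect of HAP1 and are not chance groupings, so their count does not measure chance.

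In RPE-1 31 of 40 immediate-early genes and 18 of 21 NF-kB targets rose, and in HAP1 5 and 1 did, with 5 and 1 lower. In HAP1 the authors' deposited table has 14 higher and 10 lower of 45 immediate-early genes and 2 higher and 5 lower of 23 NF-kB targets. The list calls for RPE-1 (adjusted p = 0.0539 for both) and for the difference (adjusted p = 0.166 for both) were lost with an estimated correlation. Of 2 technical explanations tested, genes too low in HAP1 to change would leave no difference among expressed members, yet the 23 members at 5 or more junction RPM in HAP1 had a median difference of -1.61 (bootstrap interval -2.51 to -0.947). The interval does not clear the bound of -1 set beforehand, so this explanation stays open. Other scalings would bring the difference toward 0, but the highest was -1.84, so scaling does not account for it. A difference in signalling between the lines was not tested.

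Within each line, the 10 splits are too few for a share under 0.05, and only the real split, 1 of 10, reached its count. Every other split mixes treated and control libraries in both groups, which widens the spread, so its low count does not measure chance. In HAP1 the real split called 3171 genes, 5849 exons, 3119 introns and 1191 splice sites, and limma called 0 in any other. At an unadjusted p under 0.05 with the same size threshold, the other splits gave at most 12, 217, 88 and 127. In RPE-1 the real split called 2595, 1699, 1267 and 492, against at most 0, 0, 0 and 3. With an unadjusted p under 0.05 and the size threshold, the other splits gave at most 45, 200, 65 and 117.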

How the results depend on the processing

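The total scaling, GC trend, 5 to 95% adjustment and background with room for the change were chosen after the data were seen, the other alternatives before. Of 382 named gene values, 342 kept direction and side of the threshold throughout, as did 13 of 80 list results, and 0 of these reversed. Of 80 named events, 65 did so under the settings that tested them, and 0 reversed. At 20 reads 61 of these events were tested, and with balanced introns 66 were. Of 42 summary results, 5 stayed the same under every setting. With 3 libraries per group, a group of 2 is assumed to spread like the others, and small changes are partly missed: 28% of HAP1 exons changed by 15 points were recovered in simulation. Whether depth sets this was not tested. The DESeq2 test was not run. Unless said otherwise, the cause was not tested.

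With the adjusted p alone, which drops the size threshold, genes higher and lower numbered 3970 and 4526 in HAP1, 3880 and 4526 in RPE-1, 4210 and 4241 for the difference and 5257 and 5032 in DMSO. Exons numbered 10236 and 8433, 5977 and 2941, and 5179 and 6344 for the difference. Splice sites numbered 3548 and 3440, 2345 and 2116, and 1725 and 1576, and introns 3185 and 20148, 2141 and 11702, and 3339 and 5984. In simulation, 8.70% of unchanged exons in HAP1 and 16.9% in RPE-1 had an adjusted p under 0.05. For introns these shares were 5.51% and 12.8%, and for splice sites 10.6% and 17.9%. The splicing counts on the adjusted p alone are therefore not counts of changed events. With an estimated correlation, camera of limma called 0 lists in HAP1, 2 in RPE-1, 0 for the difference and 5 in DMSO, and fry called 18 in HAP1 and 16 for the difference.

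On the percentage scale HAP1 splice sites numbered 302 and 317 and lower introns 1428, and RPE-1 exons 675 and 175, splice sites 69 and 60 and introns 89 and 464. At 15 points, a stricter threshold, HAP1 splice sites numbered 392 and 371 and introns 343 and 1670, RPE-1 exons 765 and 270, splice sites 152 and 155 and introns 96 and 609, and introns of the difference 256 and 503. Balanced introns, of which fewer are tested, numbered 170 and 1415 in HAP1, 33 and 609 in RPE-1 and 160 and 294 for the difference. Splice sites of the difference numbered 377 and 371 with 2 reads added and 122 and 126 with the 5 to 95% adjustment. The frame odds ratio of higher HAP1 exons was 1.11 at 15 points and 1.09 at 20 reads, and the odds ratios of retained introns that fell were 0.710 in HAP1 and 1.07 in RPE-1 with room for the change.

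The labels do not say whether the replicate numbers pair the libraries. Not every sample correlated best with its own number, and same-number correlations ran down to -0.415. An axis with 71.3% of the variance inside groups weighs on these correlations, so they cannot exclude a smaller batch shared by replicate number. With the replicate block, HAP1 splice sites numbered 388 and 376, RPE-1 exons 679 and 200, introns 74 and 580, and lower splice sites of the difference 125. For RPE-1 splice sites the block left limma 0 higher and 0 lower, with 801 at an unadjusted p under 0.05 and a difference of at least 10 points. Under the block the frame odds ratio of higher exons was 0.979 in HAP1 and 0.919 in RPE-1, both reversed, and 77.8% of RPE-1 exons were in the rMATS list.

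Leaving out each library in turn, which leaves fewer samples, gave 389 to 509 higher and 378 to 513 lower splice sites in HAP1. In RPE-1 it gave 257 to 493 lower exons, 109 to 245 higher and 102 to 261 lower splice sites, and 96 to 163 higher and 660 to 1029 lower introns. The frame odds ratio of higher RPE-1 exons ran from 0.927 to 1.04. Overlap with rMATS ran from 75.3 to 85.9% for HAP1 introns, 69.2 to 75.2% for RPE-1 exons and 75.6 to 81.7% for RPE-1 introns.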

Other observations

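Called splicing events were also counted in host genes of snoRNAs. In HAP1 13 of 18 such genes had a called event, with 7 exons higher and 1 lower, 0 introns higher and 25 lower. In RPE-1 8 of 16 had, with 6 exons higher and 0 lower, 0 introns higher and 12 lower. Of the genes known for detained introns, 24 of 29 had a called event in HAP1 (19 exons higher and 6 lower, 2 introns higher and 10 lower) and 15 of 29 in RPE-1 (11 exons higher and 0 lower, 3 introns higher and 7 lower). NMD factors had called events in 6 of 10 genes in HAP1, with 5 exons higher and 8 lower, and in 2 of 10 in RPE-1. Over all genes in HAP1, 2095 of 11004 had an exon that rose, 1877 an exon that fell, and 1543 of 11611 an intron that fell. In RPE-1 these were 1041 of 10989, 399, and 738 of 11629. The list counts of genes take a called event of any class and direction, splice sites included, whereas those over all genes are per class and direction. They are therefore not a matching background. The counts for these lists and for splicing factors were not tested against other genes.

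The tests that follow were written down beforehand, except that of replicate numbers, chosen only after the result was seen, and the changed background for NMD-only exons. Exons annotated only in NMD transcripts were the hypothesis for exons that changed. The background planned was every exon not called, which was wrong because exons already near 0 or 100% cannot move that way. Against exons with room for the change, the odds ratio was 1.51 for exons that rose in HAP1 (315 of 2950) and 2.01 in RPE-1. For exons that fell it was 2.44 and 2.08, the last with an interval from 0.925 to 4.67. Against all exons not called the values were 5.43 and 7.29 for exons that rose and 0.733 and 0.622 for those that fell. Since the background was changed after the values were seen, the hypothesis stays open.

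Most introns that changed lost retention. If more spliced mRNA of the host gene were the whole cause, genes that fell would show few falls, but in genes whose junction reads fell 68.9% of called introns went down in HAP1 and 84.9% in RPE-1. Of tested introns, 4.55% were called lower in genes that rose in HAP1, 2.22% in genes within 0.5 and 1.57% in genes that fell. Host levels may thus account for part of the falls there. Yet host levels were summed from junction reads that also count against retention, so a fall in retention itself raises them. Part of this gradient may therefore be built in. In RPE-1 the shares were 1.26%, 1.07% and 0.977%. A general drop in unspliced RNA would also lower introns that are hardly retained, and introns under 5% had a median logit2 change of -0.47 in HAP1 and -0.44 in RPE-1. By the rule set beforehand that drop fits, yet near 0 the added 0.5 reads and depth could move the logit value. In percentage, 56.2% and 45.9% of these introns fell. The rest rose or stayed unchanged, and these were not counted apart. For RPE-1 introns under 15% in the other line, the median change was 0 points. Of introns at 1 to 5% in the other line, 80.7% and 74.5% fell. Their pooled retention, with no reads added, went from 3.07% ± 0.716 to 1.99% ± 0.0374 in HAP1 and from 1.45% ± 0.0812 to 0.961% ± 0.0253 in RPE-1. HAP1 DMSO replicates 1, 2 and 3 stood at 3.11, 2.33 and 3.77%, all above the treated libraries. They lay in the same order on the axis that followed GC content, unlike the RPE-1 DMSO libraries. Whether that axis affects the size of the HAP1 fall was not tested. A general drop thus remains a possible cause in both lines, and the libraries give no way to tell less nuclear RNA in the preparation from less unspliced RNA in the cells. A biological cause stays open.

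Libraries of the same group differed along an axis with 71.3% of the variance inside groups. Genes' loadings on it correlated with GC content (Spearman 0.734) and transcript length (-0.534), with values for 12379 of 12770 genes. Same-number correlations within a line ran from -0.415 to 0.552, with 0.516 for replicate 2 of RPE-1, so libraries with the same number did not all deviate together, in a test chosen after the data were seen. GC content and length were not separated, and the source was not tested. No biological explanation was tested.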
